A study of Mus musculus with 2 samples.

How the data were processed

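RNA was measured in single cells of mouse bone marrow stroma (strain label C56BL/6, age 8 to 16 weeks), taken from crushed femurs, tibiae and pelvis with collagenase and dispase and sorted as negative for CD45, Ter119 and CD31. The labels give 1 group of 2 samples: Stroma1 with libraries 1.1 and 1.2, and Stroma2 with libraries 2.1, 2.2 and 2.3. The deposited table holds a count for each of 25289 genes in 15028 barcodes, which the authors made from inDrops reads with Bowtie 1.1.1 and the GRCm38 genome, as the submitters' processing notes name them with no order of use. The counting tool, the handling of molecular identifiers and the gene annotation are not given in the sources used here, so the values are called counts and not molecules. Per the file headers, the deposited fractions are the share of mitochondrial counts of a barcode, the authors' probability of each of 3 fates, whose values sum to 1 in a cell, and the authors' pseudotimes on 3 paths, which are evenly spaced ranks from 0 to 1. Per the file headers, the authors also deposited a potential score for each passing cell, with no unit stated. The other deposited columns used were the authors' labels of sample, library, filter and cell class. The authors' 2 coordinate columns of a plot were not used here.

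Depth was read from the counts. The authors' filter passed 948 cells of Stroma1 (1658990 counts, medians of 1523.5 counts and 799 genes) and 1899 cells of Stroma2 (3687913 counts, medians of 1324 counts and 692 genes), the numbers of final cells the series states. Passing cells had between 500 and 16562 counts and at most 14.9% mitochondrial counts. The filter did not pass 585 barcodes of Stroma1 and 1675 of Stroma2, and 9921 barcodes had no filter label, 8416 of them with under 500 counts. Shares of cells have exact Clopper-Pearson 95% intervals. A count of 0 was given a floor of 3 counts over the cells of a class in both samples, and bounds on folds were taken on the TMM scale. Intervals and floors cover counting error only.

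The authors' classes were used for the comparisons, and they may rest on the genes compared. Counts were summed per sample and class, since cells are not replicates. A class entered the tests with at least 15 cells in each sample, which left 6 classes; Pro-chondrocyte, with 4 and 10 cells, is given as values. Sums were tested with edgeR 4.0.16 (R 4.3.3): TMM normalization, filterByExpr with a minimum count of 10, and quasi-likelihood tests with a term for class and a term for sample. The design had called the counts molecular identifier counts; the same test serves both. Each class was compared with the equally weighted mean of the other 5. The p-values were adjusted by Benjamini-Hochberg over 6229 genes, and an adjusted p under 0.05 was called. Because 2 samples leave little room to estimate spread per class, the 6 classes share it (common dispersion 0.0155). The standard error of a log2 fold change was taken as its size over the square root of F. CPM was computed from raw totals per class and sample, without TMM.

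Before the data were examined, 18 gene lists were fixed: niche factors, adipogenic transcription factors, lipid genes, osteogenic and chondrogenic transcription factors, Wnt, BMP and TGF-beta, Notch, Hedgehog, progenitor markers, hormone receptors, proteases and inhibitors, angiogenic genes, glycolysis, respiratory chain (oxphos), interferon, immediate-early and cell cycle. The table held 309 of their genes, and 220 passed the count filter. The tests, the other settings apart from those named as added, the cell type markers and the rule for named genes were also fixed before the data were examined. The rule takes, in each class, the 12 highest and 6 lowest called preset genes with the same direction in both samples, and in every class Cxcl12, Kitl, Il7, Csf1, Angpt1, Vcam1, Pparg, Cebpa, Ebf3, Foxc1, Runx2, Sp7, Sox9, Grem1, Wif1, Pdgfra, Ly6a and Nes. Ly6a and Nes did not pass the count filter. Other list members named as examples were chosen after their values were seen. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, log CPM with a prior count of 2), with camera and an estimated correlation, and with fry, each adjusted over 108 tests. Fry asks whether the genes of a list move on balance in 1 direction, without a comparison with other genes.

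Niche transcripts were counted as the percent of a gene's counts in each sample that lie in a class. For links, counts of passing cells were scaled to 10000, log transformed and reduced to 2000 variable genes and 30 principal components in scanpy 1.11.5, and links among 15 nearest neighbours were divided by the number expected from class sizes, in each sample alone. The preset genes were left out of this step and of all clustering. Passing and not passing barcodes were clustered together with Leiden at resolution 1.0, and a cluster took the name of a cell type from its marker genes by a scoring rule set after an exploratory look at the clusters. Scrublet called 19 of 2847 passing barcodes doublets (0.667%) and 91 of 2260 not passing (4.03%).

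Other settings fixed in advance were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, no sample term, leaving out each sample, own clustering at Leiden resolutions 0.5 and 2.0 or with values centred within samples, count splitting, and leaving out called doublets, cells under 750 counts, classes under 30 cells in a sample, and cells with over 1% erythroid and neutrophil counts. Alternatives added after seeing the data were the comparison with MSC alone, clustering at resolution 1.0 in place of the deposited classes, 1 barcode per sample, leaving out the collagen I genes, leaving out a barcode rich in cartilage genes, and the comparison along the authors' paths. The tests were tried on simulated data with 200 changed genes among 6229: changes of 2 on the log2 scale were found in 97% of genes in MSC and Pro-osteoblast and 81% in Pre-osteoblast/chondrocyte, and changes of 1 in 82%, 69% and 28%. False calls made up 4.79%, 2.92% and 3.54% of calls. A p that misses the threshold therefore does not show that levels were the same, least of all in Pre-osteoblast/chondrocyte. The simulation changed only genes with over 200 counts, in 1 class at a time, with no sample effect and with the fitted dispersion. In the data 2449 of 6229 genes were called in Pro-osteoblast, so the simulated rates may not hold there or for genes with fewer counts. Whether a change in 1 class differs from that in another was not tested. Clustering used python-igraph 0.11.9, scikit-learn 1.9.0, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.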

Results

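The series measured RNA in single cells of mouse bone marrow stroma with inDrops droplet libraries. The marrow came from crushed femurs, tibiae and pelvis, and the cells were sorted as negative for CD45, Ter119 and CD31, the surface proteins of blood, red and endothelial cells. There was 1 group of 2 samples, Stroma1 with 2 libraries and Stroma2 with 3. The authors' filter passed 948 cells of Stroma1, with 1658990 counts and a median of 1523.5 per cell, and 1899 cells of Stroma2, with 3687913 counts and a median of 1324 per cell. The authors gave each passing cell 1 of 7 classes: MSC (read here as mesenchymal stem or stromal cell), Adipocyte progenitor, Pre-adipocyte, Osteoblast progenitor, Pre-osteoblast/chondrocyte, Pro-chondrocyte and Pro-osteoblast. The labels do not say whether the samples came from separate animals. The p-values therefore measure only how much the differences between classes varied between these samples. The deposited classes may rest on some of the genes compared here, so a difference between classes is not independent evidence that a gene marks a class.

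The series title names distinct niche populations, and the share of cells in each class shows how the sorted stroma divided. MSC was the most frequent class in both samples, with 53.0% of the cells of Stroma1 (exact 95% interval 49.7 to 56.2) and 42.9% of Stroma2 (40.7 to 45.2). Adipocyte progenitor held 17.4% and 15.7%, Osteoblast progenitor 15.2% and 13.7%, and Pre-adipocyte 6.96% and 7.64%. Pre-osteoblast/chondrocyte held 2.64% and 3.48%. Pro-chondrocyte held 4 cells (0.422%) and 10 cells (0.527%). Pro-osteoblast differed most between the samples, with 42 cells or 4.43% in Stroma1 (3.21 to 5.94) and 305 cells or 16.1% in Stroma2 (14.4 to 17.8). In the libraries of Stroma1 its share was 3.97% and 4.95%, and in those of Stroma2 it was 20.3%, 13.5% and 14.0%. With each barcode kept once per sample, a choice made after seeing the data, it was 3.60% and 12.5%. With 1 group of 2 samples no share was tested, and the intervals cover counting error only.

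**Figure D1:**
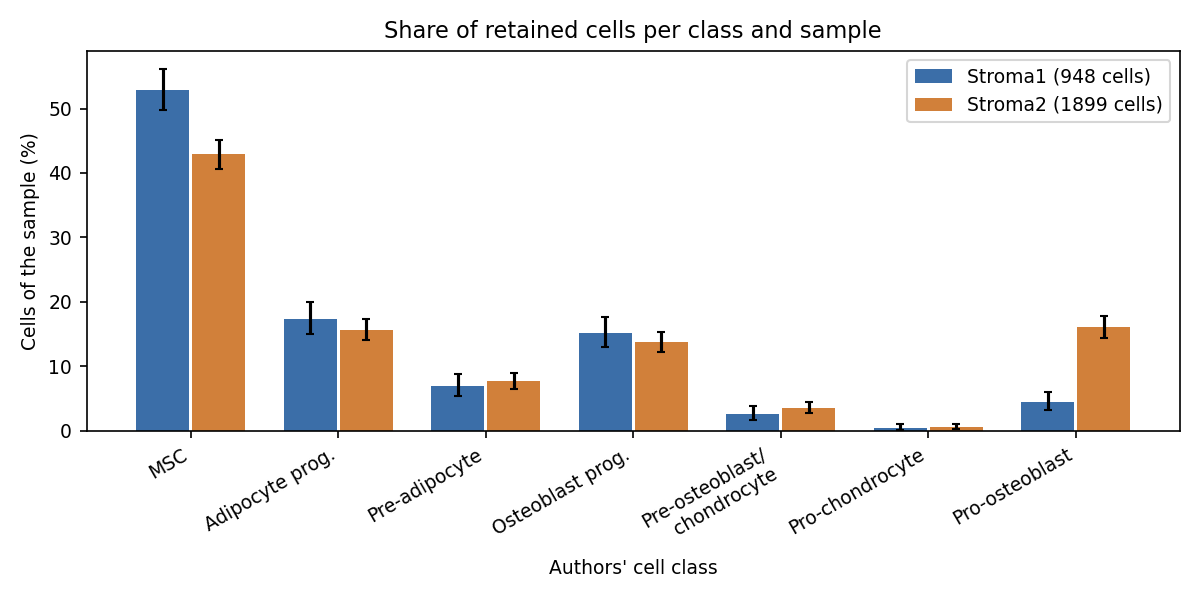
Percent of passing cells in each of the authors' 7 classes, as bars for Stroma1 and Stroma2 with exact 95% intervals. MSC stands at 53.0% and 42.9%, and Pro-osteoblast at 4.43% and 16.1%.

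The first comparison asked which preset genes set MSC apart from the mean of the other 5 classes tested. Cxcl12, the chemokine that holds blood stem cells in the marrow (GRCm38 chromosome 6, 117168535 to 117181367), reached 64576 ± 1539 CPM (counts scaled by the total of a class and sample; mean ± SD, n = 2 samples here and below) and rose by 1.97 on the log2 scale (SE 0.12, adjusted p = 2.3e-24). Kitl, the ligand of the Kit receptor (chromosome 10, 100015630 to 100100416), stood at 1465 ± 54.9 CPM and rose by 1.82 (SE 0.11, adjusted p = 1.2e-24). Il34, a ligand of the Csf1 receptor (chromosome 8, 110741829 to 110805924), rose by 2.85 (SE 0.19), and Angpt1, a ligand of the Tie receptors (chromosome 15, 42424723 to 42676977), by 2.42 (SE 0.23). The secreted Wnt binder Sfrp4 (chromosome 13, 19623104 to 19632994) rose by 2.29 (SE 0.11), and the transcription factors Cebpa and Ebf3 by 2.05 (SE 0.16) and 1.94 (SE 0.12).

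Of 19 niche factor genes measured in MSC, 13 rose and 1 fell, with a median log2 change of 1.59 (camera adjusted p = 7.6e-05, and adjusted p = 0.238 with an estimated correlation). Of 12 genes of adipogenic transcription factors, 6 rose, among them Klf15 by 2.48, and 1 fell (camera adjusted p = 0.00297, and adjusted p = 0.288 with an estimated correlation). Of 11 interferon genes, 7 rose, such as Ifit3 by 1.60 and Irf7 by 1.15 (camera adjusted p = 0.000999, and adjusted p = 0.115 with an estimated correlation). The mean compared with holds Pro-osteoblast, where niche factors, adipogenic transcription factors and interferon genes had medians of −4.16, −2.74 and −2.19. Osteogenic transcription factors and respiratory chain genes, given below, had medians of 1.62 and 0.64 in Pro-osteoblast. In Pre-osteoblast/chondrocyte the interferon median was −0.57. Of 10 osteogenic transcription factors, none rose and 6 fell, with Mef2c at −1.65, Twist1 at −1.38 and Sp7, a regulator that osteoblasts need, at −1.35 (camera adjusted p = 0.000132, and adjusted p = 0.115 with an estimated correlation). Of 18 immediate-early genes, which respond within minutes to stimulation or stress, 17 fell and none rose, with Ier3 at −2.05 (camera adjusted p = 3.9e-13, and adjusted p = 0.115 with an estimated correlation), against a mean that holds both adipocyte classes. Proteases and their inhibitors fell in 6 of 13 genes and rose in 1, with Mmp2, a gelatinase (chromosome 8, 92827291 to 92853420), at −2.28 (camera adjusted p = 0.00211, and adjusted p = 0.178 with an estimated correlation). Respiratory chain genes fell in 5 of 23 (camera adjusted p = 0.0389, and adjusted p = 0.178 with an estimated correlation), beside mitochondrial shares of counts of 4.02% and 3.98% in the samples, and cell cycle genes in 1 of 8 (camera adjusted p = 0.0451, and adjusted p = 0.413 with an estimated correlation). In all, 53 of 220 preset genes rose and 59 fell by edgeR at an adjusted p under 0.05 over 6229 genes, or 62 and 60 adjusted over the list alone. Pdgfra at 0.26 (adjusted p = 0.107) and Runx2 at −0.15 (adjusted p = 0.588) did not pass. Genes with a class at 0 counts have no bounded fold here and are given as levels: Chrdl1, a BMP antagonist, had 1505 ± 115 CPM in MSC, Fgf7 had 213 ± 6.98, Rspo2 had 171 ± 30.3, Il7 had 89.6 ± 22.1 and Pparg had 66.2 ± 5.35. The call of Sp7 ended with classes from clustering at Leiden resolution 2.0 (−0.57), and that of Wif1, at −1.43 in the deposited classes, ended with count splitting (−0.25).

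Adipocyte progenitor shared high niche factor levels with MSC and stood out by immediate-early genes. Against the mean of the other 5 classes, the stress factor Atf3 rose by 3.40 (SE 0.27, adjusted p = 6.1e-19), the neutrophil chemokine Cxcl1 by 3.10 (SE 0.16, adjusted p = 1.5e-29) to 808 ± 80.4 CPM, and the nuclear receptor Nr4a1 (chromosome 15, 101254269 to 101274795) by 2.88 (SE 0.14, adjusted p = 1.3e-31). Cxcl12 rose by 2.01 (SE 0.12), the BMP antagonist Grem1 by 2.42 and Ebf3 by 2.23. Sp7 fell by 1.96 (SE 0.32) and Mmp2 fell by 2.07 (SE 0.27). Against MSC alone, a comparison added after seeing the data, Atf3 rose by 4.32 (SE 0.34), Cxcl1 by 4.16 (SE 0.20) and Nr4a1 by 3.77 (SE 0.17), while Cxcl12 was at 0.04 (adjusted p = 0.984). Sfrp4, at −0.45 (SE 0.12, adjusted p = 0.0118), was the 1 gene lower than in MSC, beside 44 higher.

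In Adipocyte progenitor all 18 immediate-early genes rose, with a median log2 change of 2.01 (camera adjusted p = 1.3e-20, and adjusted p = 0.115 with an estimated correlation). Against MSC alone all 18 rose as well, with a median of 2.45 and an adjusted p = 0.0438 with an estimated correlation. Of 19 niche factor genes 17 rose, with a median of 2.01 (camera adjusted p = 4.8e-11, and adjusted p = 0.144 with an estimated correlation). Of 12 adipogenic transcription factors 8 rose (camera adjusted p = 0.000228, and adjusted p = 0.196 with an estimated correlation), while 2 of 9 lipid genes rose, Fabp4 by 1.85 and Angptl4 by 1.02. Of 8 Notch genes 4 rose: Hes1 by 1.63, Notch3 by 1.44, Heyl by 1.25 and Notch1 by 1.10 (camera adjusted p = 0.00414, and adjusted p = 0.141 with an estimated correlation). BMP and TGF-beta genes rose in 9 of 21 and fell in 1 (camera adjusted p = 0.0103, and adjusted p = 0.178 with an estimated correlation), and interferon genes rose in 7 of 11 (camera adjusted p = 0.00042, and adjusted p = 0.115 with an estimated correlation). Along the authors' adipocyte path, from MSC to both adipocyte classes, 3 of 12 adipogenic factors rose and 1 fell. None of 12 interferon genes was called along it. Of 8 Notch genes 2 rose along it, Hes1 by 3.09 and Hey1 by 2.47. Heyl fell by 0.97 and Notch2 by 1.15, while Notch3 at 0.21 and Notch1 at 0.70 did not pass. Adipocyte progenitor was compared above with a mean that holds Pro-osteoblast. There adipogenic factors, Notch genes and interferon genes had medians of −2.74, −2.98 and −2.19. Osteogenic transcription factors fell in 4 of 10 and rose in 1, such as Mef2c at −1.81 (camera adjusted p = 0.00418, and adjusted p = 0.149 with an estimated correlation). No cell cycle gene passed on its own, and the list of 8 was lower (median −1.33, camera adjusted p = 0.0226, and adjusted p = 0.355 with an estimated correlation). In all, 85 preset genes rose and 16 fell by edgeR, or 89 and 20 adjusted over the list alone. The chemokine Ccl2 rose by 2.66 (SE 0.27), but its call ended with the DESeq2 Wald test (2.44). Mmp9 had 1 count in each sample and a fitted value of −2.94, and this turned to 2.83 with classes from clustering at Leiden resolution 0.5. The cytokine Il6 stood at 161 ± 130 CPM, from 81 counts in Stroma1 and 33 in Stroma2.

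Pre-adipocyte had higher mean levels of Fosb, Nr4a1, Cxcl1 and Ccl2 than Adipocyte progenitor, a difference that was not tested. Ccl2, the monocyte chemokine, rose by 5.82 (SE 0.21, adjusted p = 6.0e-41) to 1992 ± 747 CPM, and Cxcl1 by 5.09 (SE 0.15, adjusted p = 1.9e-47) to 2399.5 ± 567. Nr4a1 rose by 4.98 (SE 0.13, adjusted p = 1.0e-51) and Fosb, a subunit of the AP-1 factor (chromosome 7, 19302696 to 19310051), by 3.93 (SE 0.10, adjusted p = 1.4e-51), to 5891 ± 168 CPM. Il6 stood at 511 ± 151 CPM beside 7.62 ± 3.01 in MSC, and was at least 147-fold higher than in Pro-osteoblast, from a floor of 3 counts over both samples of that class on the TMM scale of the log2 changes. Tnfsf11, the osteoclast differentiation factor, stood at 544 ± 105 CPM, at least 156-fold higher than in Pro-osteoblast by the same floor. Against MSC alone, Cxcl1 rose by 5.81 and Fosb by 4.44, Sfrp4 fell by 0.87 (SE 0.15, adjusted p = 1.8e-06), and Cxcl12 at −0.21 (adjusted p = 0.550) and Cebpa at −0.35 (adjusted p = 0.276) did not pass.

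In Pre-adipocyte all 18 immediate-early genes rose, with a median log2 change of 2.99 (camera adjusted p = 5.0e-19, and adjusted p = 0.115 with an estimated correlation). Of 19 niche factor genes 17 rose (median 2.17, camera adjusted p = 3.6e-10, and adjusted p = 0.149 with an estimated correlation), and of 12 adipogenic transcription factors 8 rose (median 1.57, camera adjusted p = 8.6e-05, and adjusted p = 0.178 with an estimated correlation). Along the authors' adipocyte path, from MSC to both adipocyte classes, 5 of 18 niche factors rose and 2 fell. Of 12 adipogenic factors 3 rose and 1 fell along it. Pre-adipocyte was compared above with a mean that holds Pro-osteoblast, where these lists had medians of −4.16 and −2.74. Of 9 lipid genes 1 rose and none fell (median 0.45, camera adjusted p = 0.174). BMP and TGF-beta genes rose in 12 of 21 (camera adjusted p = 0.00035, and adjusted p = 0.115 with an estimated correlation). Respiratory chain genes fell in 5 of 23, among them Ndufa1 at −1.43 and Ndufa2 at −1.36 (camera adjusted p = 0.00109, and adjusted p = 0.115 with an estimated correlation). The mean compared with holds Pro-osteoblast, where the respiratory chain median was 0.64. Along the adipocyte path 1 of 23 respiratory chain genes rose and none fell (median 0.0046). The mitochondrial share of counts was 2.69% and 2.95% in this class, beside 4.02% and 3.98% in MSC and 7.30% and 6.75% in Osteoblast progenitor. The glycolysis genes Hk2 and Ldha rose by 2.43 and 1.65, and the vessel growth factor Vegfa by 2.98. Osteogenic transcription factors did not shift as a list; Atf4 rose by 1.45, while Mef2c fell by 2.08 and Sp7 by 1.86 (SE 0.42). In all, 86 preset genes rose and 20 fell by edgeR, or 91 and 25 adjusted over the list alone. Sox9, a cartilage regulator, and Bmp2 leaned on Stroma2, with 12 and 155 counts for Sox9 and 20 and 182 for Bmp2. Their rises of 4.12 (SE 0.29) and 4.63 (SE 0.28) became 1.95 and 3.09 without replicate 2, and 2.99 and 2.83 without both copies of 1 barcode of Stroma2 rich in cartilage genes, left out after seeing the data. Blood genes made up 2110 CPM of this class in Stroma1 and 428 CPM in Stroma2.

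In Osteoblast progenitor Wif1, a secreted Wnt inhibitor (chromosome 10, 121033960 to 121100650), rose by 2.43 (SE 0.10, adjusted p = 3.8e-35) to 2563 ± 294 CPM, beside 284 ± 1.48 in MSC. The collagenase Mmp13 (chromosome 9, 7272514 to 7283331) rose by 1.88 (SE 0.10, adjusted p = 1.3e-27) to 4323 ± 732 CPM, and Sp7 (chromosome 15, 102356606 to 102367182) by 1.20 (SE 0.22, adjusted p = 2.3e-05) to 208 ± 3.83 CPM. The Wnt agonist Rspo3 rose by 2.09 (SE 0.29), the growth factor Igf1 by 2.09 (SE 0.19) and the Tie ligand Angpt4 by 2.46 (SE 0.22). The mean compared with holds Pro-osteoblast, and Rspo3 and Igf1 fell by 5.05 and 3.97 late on the authors' osteoblast path. The end of the authors' chondrocyte path was mostly Osteoblast progenitor and its start was MSC. Along it Rspo3 at 0.50 (edgeR adjusted p = 0.325) and Igf1 at 0.37 (edgeR adjusted p = 0.184) did not pass, while Angpt4 rose by 2.67. Against MSC alone, Wif1 rose by 3.22 (SE 0.14), Mmp13 by 2.89 (SE 0.14) and Sp7 by 2.13 (SE 0.27), while Sfrp4 fell by 2.15 (SE 0.15), Il34 by 2.10 (SE 0.21) and Kitl by 0.89.

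Of 17 Wnt genes in Osteoblast progenitor 6 rose and none fell, but the list did not pass camera (adjusted p = 0.0892). Of 13 protease and inhibitor genes 6 rose, and of 21 BMP and TGF-beta genes 7 rose, again with no list shift. All 18 immediate-early genes fell, with a median log2 change of −1.22 (camera adjusted p = 4.8e-20, and adjusted p = 0.115 with an estimated correlation). The immediate-early genes were compared here with a mean that holds both adipocyte classes; against MSC alone the list did not shift (median −0.15, camera adjusted p = 0.687). Of 11 interferon genes 3 rose: Bst2 by 1.05, Ifi27 by 0.72 and Ifitm3 by 0.50 (camera adjusted p = 0.00266, and adjusted p = 0.122 with an estimated correlation). The mean compared with holds Pro-osteoblast, where the interferon median was −2.19, and the list's median was 0.75 here and 0.85 in MSC. Of 12 glycolysis genes 2 fell, Hk2 at −1.08 and Ldha at −0.95 (camera adjusted p = 0.0363, and adjusted p = 0.215 with an estimated correlation). This mean holds both adipocyte classes, and late on the adipocyte path Hk2 and Ldha rose by 3.31 and 1.62. Late on the chondrocyte path, mostly Osteoblast progenitor, 2 of 12 glycolysis genes rose and none fell. Hk2 rose there by 1.30, and Ldha at 0.14 did not pass. In all, 48 preset genes rose and 30 fell by edgeR, or 57 and 37 adjusted over the list alone. Of the named genes, 10 changed direction in at least 1 alternative, mostly with classes from clustering the cells again: Cxcl12 went from 1.40 to −0.49, Cebpa from 1.70 to −0.47, and Nr4a1 from −1.82 to 0.91. Clustering again changed both the cells of the class and the mean it was compared with, since 4 or 5 of the 6 classes were recovered, and these effects were not separated. Wif1, Mmp13 and Sp7 kept both direction and call in every alternative with a test, and Mmp13 was at 4.54 with clustering at Leiden resolution 0.5.

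Pre-osteoblast/chondrocyte was led by matrix-degrading enzymes. Mmp13 rose by 4.94 (SE 0.09, adjusted p = 1.2e-61) to 22865 ± 65.3 CPM, and the gelatinase Mmp9 (chromosome 2, 164940780 to 164955850) rose by 6.61 (SE 0.36, adjusted p = 4.2e-28) to 636 ± 259 CPM. The inhibitor Timp1 rose by 3.95 (SE 0.23), Mmp2 by 2.70 (SE 0.19) and Wif1 by 2.01 (SE 0.14), to 1785 ± 168 CPM. Cxcl12 fell by 2.98 (SE 0.19, adjusted p = 2.0e-23) to 3292 ± 415 CPM, Kitl fell by 2.09 (SE 0.29) and Vcam1, an adhesion molecule for blood cells, fell by 2.27. Chrdl1 had 0 counts and was at least 76.6-fold lower than in MSC, from 3 counts over both samples of the class on the TMM scale, and Rspo2, Il7 and Pparg, also at 0, were at least 8.68-fold, 4.56-fold and 3.37-fold lower.

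Of 13 protease and inhibitor genes in this class 8 rose and 1 fell (median 1.45, camera adjusted p = 0.000767, and adjusted p = 0.172 with an estimated correlation). Of 8 cell cycle genes 5 rose (median 3.62, camera adjusted p = 0.000189, and adjusted p = 0.178 with an estimated correlation). The cell cycle genes rested on few counts: Cdk1, the mitotic kinase, had 9 and 7 counts and rose by 4.26, Ube2c had 11 and 10 and rose by 4.13, and Birc5 had 6 and 7 and rose by 3.50. Niche factors fell in 9 of 19 genes and rose in 1, with a median of −2.27, or −1.24 with zero-count genes at their floor (camera adjusted p = 6.9e-07, and adjusted p = 0.178 with an estimated correlation). Adipogenic transcription factors fell in 4 of 12 (camera adjusted p = 0.00528, and adjusted p = 0.307 with an estimated correlation), and BMP and TGF-beta genes in 7 of 21 with 1 higher (camera adjusted p = 0.0373, and adjusted p = 0.196 with an estimated correlation). Respiratory chain genes rose in 2 of 23, Atp5b by 0.67 and Cox4i1 by 0.59 (camera adjusted p = 0.0419, and adjusted p = 0.178 with an estimated correlation), beside mitochondrial shares of 8.52% and 6.25%. Of 10 osteogenic transcription factors 4 rose and none fell, with no list shift: Mef2c rose by 1.94 and Sp7 by 1.08 (SE 0.34, adjusted p = 0.0234). Immediate-early genes did not shift against the other 5 classes, with 3 higher and 3 lower of 18, but against MSC alone 11 rose and none fell (median 0.81, camera adjusted p = 0.00197, and adjusted p = 0.374 with an estimated correlation). In all, 35 preset genes rose and 35 fell by edgeR, or 41 and 44 adjusted over the list alone. The call of Sp7 ended with no filter on low counts (0.86). Runx2, a regulator of bone formation, rose by 0.90 (SE 0.22, adjusted p = 0.0019), but it was −0.02 without replicate 2 and 1.21 without replicate 1, and its call ended with the DESeq2 Wald test (0.79).

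Pro-osteoblast stood out by high bone regulators and low niche factors. Sp7 rose by 2.90 (SE 0.19, adjusted p = 1.0e-23) to 261 ± 46.4 CPM, Mef2c by 3.79 (SE 0.20, adjusted p = 2.0e-29) and Twist1 by 3.01 (SE 0.19). Mmp2 rose by 4.25 (SE 0.12, adjusted p = 2.7e-49) to 1082 ± 34.5 CPM, the membrane protease Mmp16 by 5.42 (SE 0.40) and Bmp3 by 5.51 (SE 0.36). Cxcl12 fell by 4.12 (SE 0.20, adjusted p = 5.5e-32) to 1085 ± 853 CPM, Kitl fell by 4.14 (SE 0.25) to 33.9 CPM and Csf1, a growth factor of macrophages and osteoclasts, fell by 4.24 (SE 0.22) to 28.0 CPM. Tnfsf11 and Fgf7 had 0 counts and were at least 28.4-fold and 49.8-fold lower than in MSC, from 3 counts over both samples on the TMM scale. Collagen I genes held 39.0% and 42.7% of the counts of this class and at most 4.02% in any other class tested. CPM from raw totals is therefore lower for its other genes than on the TMM scale, where the factors were 0.590 and 0.506, beside 1.25 in MSC.

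Of 10 osteogenic transcription factors in Pro-osteoblast 6 rose and 1 fell (median 1.62, camera adjusted p = 0.011, and adjusted p = 0.172 with an estimated correlation). Of 23 respiratory chain genes 13 rose and none fell, with Ndufa1 at 2.43 and Cox5a at 0.97 (camera adjusted p = 0.000467, and adjusted p = 0.115 with an estimated correlation), beside mitochondrial shares of 4.35% and 3.47%. Niche factors fell in 13 of 19 and rose in 2 (median −4.16, camera adjusted p = 9.5e-08, and adjusted p = 0.178 with an estimated correlation) and adipogenic transcription factors in 9 of 12 (camera adjusted p = 8.3e-05, and adjusted p = 0.178 with an estimated correlation). Of 8 Notch genes 7 fell, with Notch3 at −4.62 and Heyl at −4.83 (camera adjusted p = 0.00035, and adjusted p = 0.115 with an estimated correlation). Of 11 interferon genes 10 fell, such as Irf7 at −4.16 and Ifitm3 at −3.19 (camera adjusted p = 0.000102, and adjusted p = 0.115 with an estimated correlation). BMP and TGF-beta genes fell in 13 of 21 and rose in 2 (camera adjusted p = 0.00635, and adjusted p = 0.172 with an estimated correlation). Angiogenic genes fell in 6 of 10 and rose in 1, with Vegfa at −1.49 and Vegfc at −4.32 (camera adjusted p = 0.00242, and adjusted p = 0.122 with an estimated correlation). Immediate-early genes fell in 17 of 18 (median −2.62, camera adjusted p = 3.6e-09, and adjusted p = 0.149 with an estimated correlation). The mean compared with holds both adipocyte classes; against MSC alone 11 fell and 1 rose (median −1.14, camera adjusted p = 0.0101, and adjusted p = 0.446 with an estimated correlation). In all, 41 preset genes rose and 108 fell by edgeR, or 42 and 111 adjusted over the list alone. Pth1r, the parathyroid hormone receptor, rose by 2.05, and Esr1, an estrogen receptor, fell by 2.45. The homeobox gene Dlx3 stood at 45.8 ± 4.39 CPM, at least 59.7-fold higher than in MSC by the floor of 3 counts on the TMM scale, but its edgeR call ended with the DESeq2 Wald test. Runx2 rose by 0.46 (adjusted p = 0.0305), and its call ended with DESeq2 size factors (0.36).

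**Figure D2:**
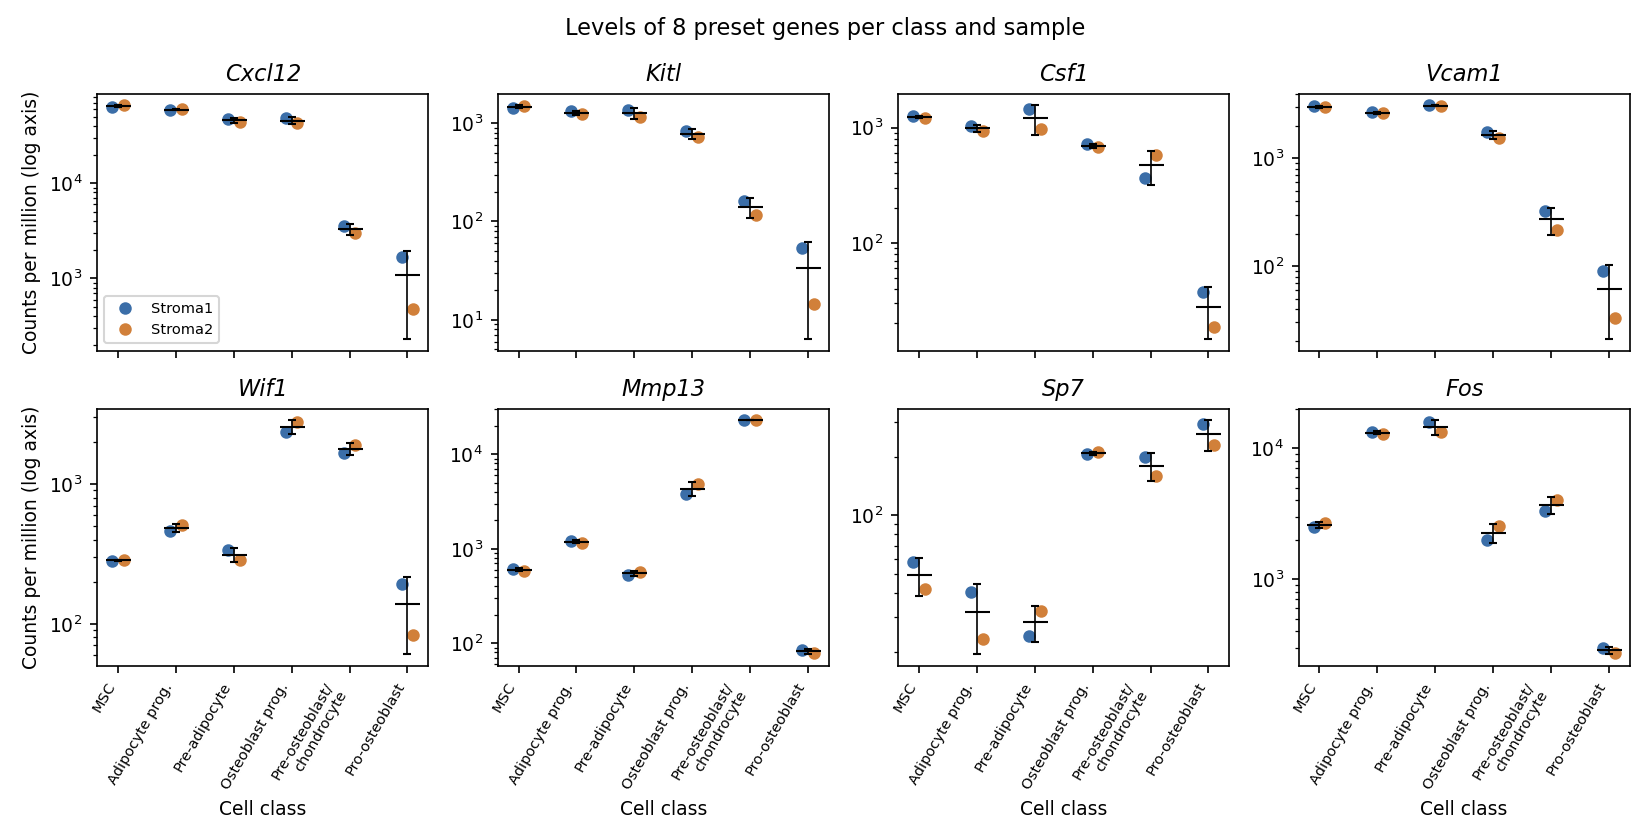
CPM on a log axis for Cxcl12, Kitl, Csf1, Vcam1, Wif1, Mmp13, Sp7 and Fos in the 6 classes tested, with a point per sample and the mean and SD. Cxcl12 lies between 64576 in MSC and 1085 in Pro-osteoblast, and Mmp13 is highest in Pre-osteoblast/chondrocyte at 22865. CPM is without TMM and is lower in Pro-osteoblast than on the TMM scale, since collagen I genes hold a large part of its counts.

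Pro-chondrocyte had 14 cells in all and was not tested, and its genes are named after their values were seen. Spp1 (osteopontin), Dmp1 and Mepe, matrix proteins of bone cells, stood at 204307, 15888 and 15391 CPM over both samples, beside 5351, 221 and 4.13 in the other classes together. Acan, Col2a1 and Sox9, markers of cartilage cells, had 0 counts in it. A count of 0 in this class allows up to 186 CPM.

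Which class holds the transcripts of each niche factor was asked as a share of the sample total. MSC, with 47.9% of the cells on average, held 55.3% ± 0.579 (mean ± SD, n = 2) of Cxcl12 transcripts, 56.8% ± 0.833 of Kitl, 55.8% ± 0.943 of Csf1, 55.5% ± 1.72 of Vcam1, 64.1% ± 3.58 of Angpt1 and 49.3% ± 8.17 of Il7. Adipocyte progenitor, with 16.5% of the cells, held 22.8% ± 0.349 of Cxcl12, 22.2% ± 0.746 of Kitl and 22.0% ± 0.104 of Vcam1. Osteoblast progenitor held 13.7% ± 0.282 of Cxcl12 and Pre-adipocyte 7.42% ± 0.340. Pro-osteoblast held 0.475% ± 0.134 of Cxcl12, 0.661% of Kitl and 0.812% of Csf1. These shares were not tested.

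The title also names differentiation paths, and links between neighbouring cells show which classes lie close in expression. Within each sample, Adipocyte progenitor and Pre-adipocyte had 2.11 ± 0.229 times the links expected from their sizes, and Osteoblast progenitor and Pre-osteoblast/chondrocyte 1.83 ± 0.0761 times. MSC had 1.01 ± 0.000841 times the expected links with Osteoblast progenitor and 0.598 ± 0.00812 times with Adipocyte progenitor. Pre-osteoblast/chondrocyte and Pro-osteoblast had 0.549 ± 0.139 times, and MSC and Pro-osteoblast 0.0109 ± 0.0155 times. Pre-osteoblast/chondrocyte and Pro-chondrocyte had 9.66 ± 2.41 times, a value that rests on 14 Pro-chondrocyte cells. The links were not tested, and a link carries no direction.

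The authors' pseudotimes order cells along 3 paths, and the last against the first of 5 equal parts of each path was compared per sample, a comparison added after seeing the data. Late on the adipocyte path all 18 immediate-early genes rose (median 4.17), with Fosb at 5.56 (SE 0.15), while Sfrp4 fell by 1.14 (SE 0.11) and Cxcl12 by 0.16 (SE 0.04, adjusted p = 0.0064). Immediate-early genes also rose late on the chondrocyte path, in 12 of 17 with none lower (median 0.95), while on the osteoblast path 2 of 16 rose and 6 fell. Late on the osteoblast path Mmp2 rose by 5.65 (SE 0.25) and Sp7 by 4.22 (SE 0.34), Cxcl12 fell by 4.88 (SE 0.23), and 13 of 17 niche factors and all 11 interferon genes fell. Late on the chondrocyte path Mmp13 rose by 5.38 (SE 0.12) and Wif1 by 4.17 (SE 0.16), Il34 fell by 3.90, and 9 of 11 protease and inhibitor genes rose. By edgeR 55 preset genes rose and 12 fell late on the adipocyte path, 43 and 84 on the osteoblast path, and 53 and 39 on the chondrocyte path. The end of the osteoblast path held 50 cells of Stroma1 and 336 of Stroma2, and 84.0% and 90.2% of them were Pro-osteoblast. The end of the adipocyte path was 52.4% and 56.9% Pre-adipocyte and otherwise mostly Adipocyte progenitor. The end of the chondrocyte path was 68.8% and 67.2% Osteoblast progenitor, 22.3% and 25.5% Pre-osteoblast/chondrocyte and 3.57% and 4.05% Pro-chondrocyte. Its late values are sums over these classes, and shares of cells do not give the part of each class in a value. Mmp13, for example, was higher in Pre-osteoblast/chondrocyte than in Osteoblast progenitor. The authors' deposited potential had medians of 0.179 and 0.178 in the MSC of the samples, 0.128 and 0.106 in Osteoblast progenitor, 0.0963 and 0.0948 in Adipocyte progenitor, −0.245 and −0.222 in Pre-adipocyte, −0.304 and −0.322 in Pre-osteoblast/chondrocyte, −0.521 and −0.527 in Pro-chondrocyte, and −0.551 and −0.556 in Pro-osteoblast. The authors made the classes, the pseudotimes and the scores from these same cells, so their order is not independent evidence.

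Because the sort was against blood and endothelial cells, the share of other cell types was measured. Among passing cells, clusters led by endothelial, B-lineage or neutrophil markers held 3 of 948 cells (0.316%, exact 95% interval 0.0653 to 0.922) and 8 of 1899 (0.421%, 0.182 to 0.828). Among barcodes the authors' filter did not pass, clusters of non-stromal types held 364 of 585 (62.2%, 58.2 to 66.2) in Stroma1 and 625 of 1675 (37.3%, 35.0 to 39.7) in Stroma2. Clusters that the marker rule left unnamed held 508 (53.6%) and 850 (44.8%) of the passing cells and 174 and 936 of the barcodes not passing, or 221 (23.3%) and 411 (21.6%), and 215 and 1029, at Leiden resolution 0.5, and the share of other types among those not passing is undetermined. In passing cells the genes of the main other types were low in Stroma1 and Stroma2: erythroid genes made up 85.0 and 55.9 CPM beside 9613 and 5854 in barcodes not passing, neutrophil genes 180 and 77.0 beside 8475 and 1042, B-lineage genes 47.0 and 74.6 beside 1101 and 1381, and endothelial genes 22.3 and 28.7 beside 740 and 305. Osteoclast genes went the other way, at 183 and 178 CPM in passing cells beside 74.8 and 23.3 in barcodes not passing. No cluster was named as monocytes, T cells or osteoclasts, so the share of those cells was not measured.

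**Figure D3:**
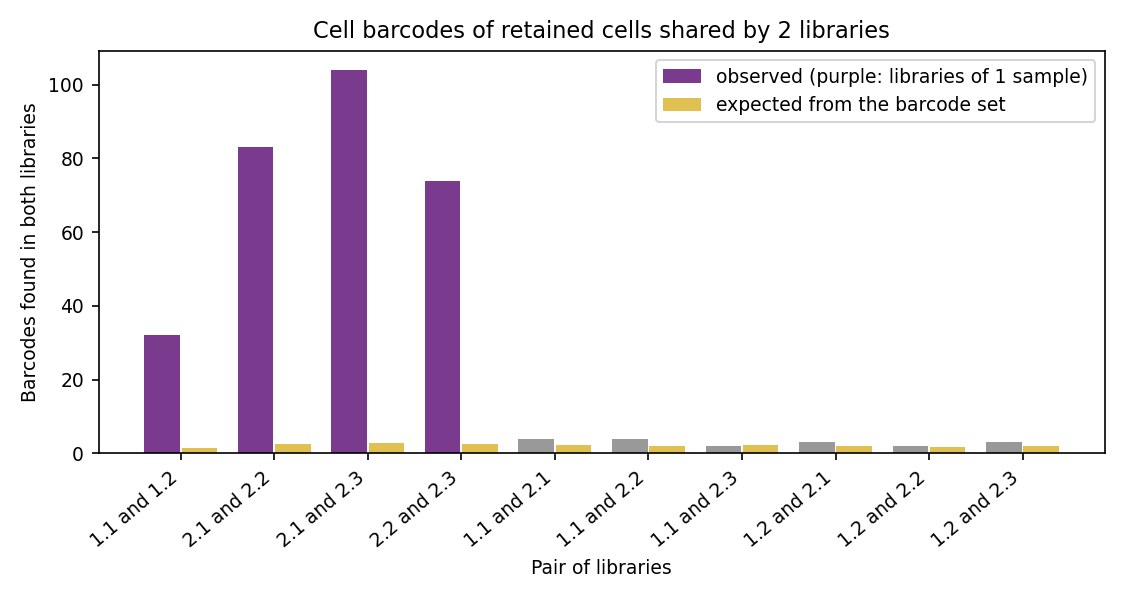
Number of cell barcodes found in both libraries of each pair, beside the number expected by chance, for passing barcodes, with pairs of the same sample in purple and pairs of different samples in grey. Within samples 293 barcodes were shared where 9.66 were expected, and between samples 18 where 12.2 were expected.

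Over the 18 preset lists and 6 classes, 39 of 108 tests passed camera with its preset correlation. With an estimated correlation none of 108 passed by camera, where 28 had an unadjusted p under 0.05 and the lowest adjusted p was 0.115, and by fry 64 passed. Lists of lipid genes (lowest camera adjusted p = 0.174, in Pre-adipocyte), chondrogenic factors (0.246, Pre-osteoblast/chondrocyte), Wnt genes (0.0892, Osteoblast progenitor), Hedgehog genes (0.428, MSC), progenitor markers (0.617, MSC) and hormone receptors (0.174, Pro-osteoblast) passed camera in no class, and each passed fry in at least 1 class. By fry Wnt genes were higher in Osteoblast progenitor (adjusted p = 0.00591) and lower in Pro-osteoblast (adjusted p = 0.00113), where 5 of 17 rose and 5 fell: Lrp5 rose by 1.73 while Sfrp4 fell by 4.25. Chondrogenic factors had 3 tested genes. Sox9 was higher in Pre-adipocyte, where it leans on 1 barcode of Stroma2, and in Adipocyte progenitor, and lower in Pro-osteoblast; Trps1 was lower in Adipocyte progenitor and higher in Pre-osteoblast/chondrocyte. By fry the list was higher in Pre-adipocyte (adjusted p = 0.00269) and lower in Pro-osteoblast (adjusted p = 0.00113). In Pro-osteoblast fry also gave lower hormone receptors (adjusted p = 0.00113, 8 of 14 lower and 2 higher), lipid genes (adjusted p = 0.0185, 2 of 9 lower and 1 higher), Hedgehog genes (adjusted p = 0.0371, 1 of 3 lower) and progenitor markers (adjusted p = 0.0471, 4 of 9 lower and 3 higher, among them Cd200 by 1.81). The median and the camera direction differed in sign for Wnt genes in MSC (−0.10, tested as higher), Pre-adipocyte (0.13, lower) and Pro-osteoblast (0.15, lower), for angiogenic genes in MSC (0.26, lower) and Pre-osteoblast/chondrocyte (−0.02, higher), for hormone receptors in Adipocyte progenitor (0.22, lower) and Pre-osteoblast/chondrocyte (−0.08, higher), for osteogenic factors and Hedgehog genes in Pre-adipocyte (0.06 and 0.12, lower) and Osteoblast progenitor (0.02 and 0.10, lower), and for progenitor markers in Pro-osteoblast (0.02, lower). None of these passed camera. With zero-count genes at their floor, 48 of the 108 medians took in such genes, and the median of osteogenic factors in Pre-adipocyte went from 0.06 to −0.30, that of cell cycle genes there from −0.45 to 0.03, and that of cell cycle genes in Adipocyte progenitor from −1.33 to −1.88.

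**Figure D4:**
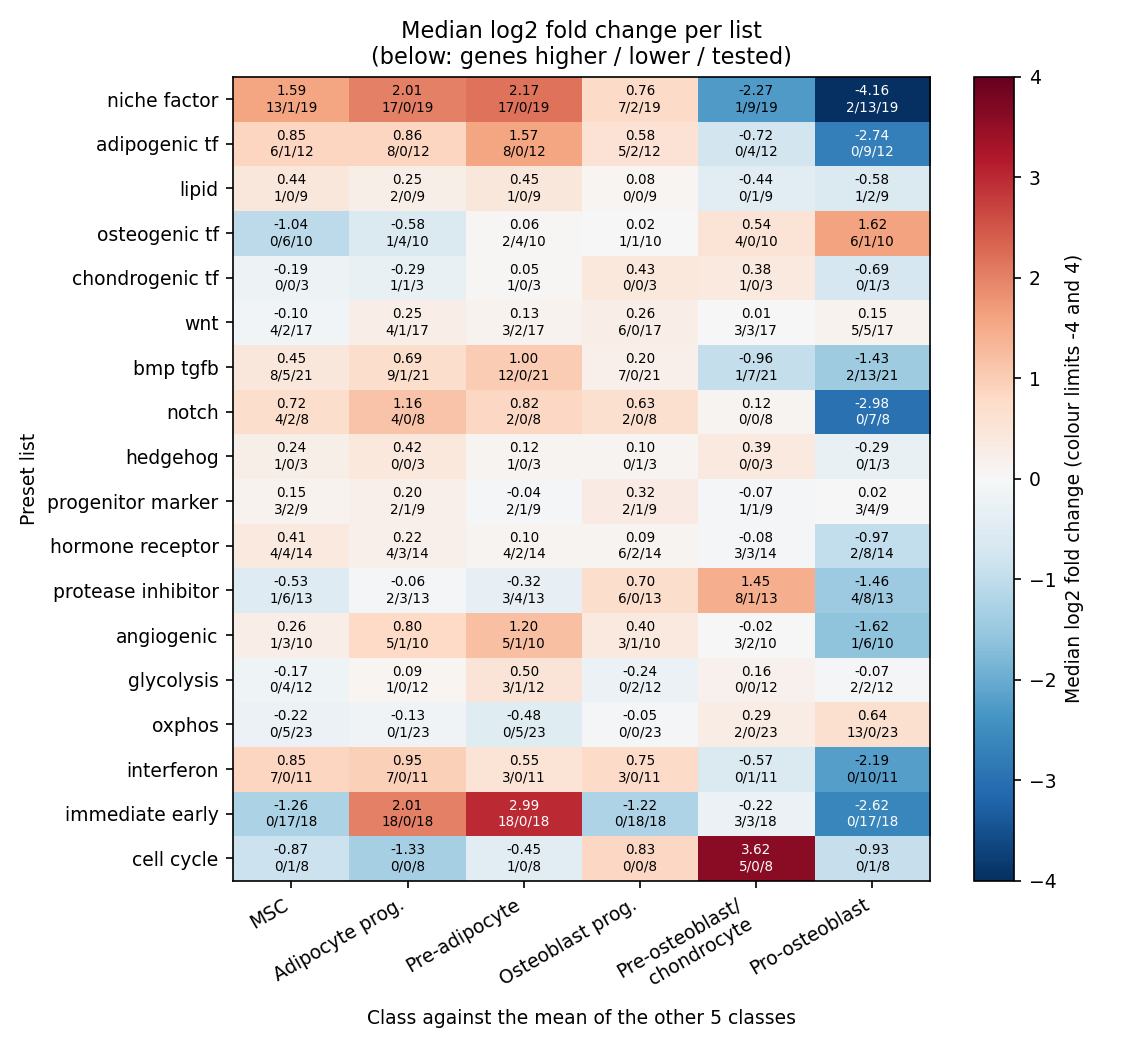
Median log2 fold change of each of the 18 preset lists in each of the 6 classes against the mean of the other classes, as colours limited to −4 and 4, with the numbers of genes higher, lower and tested in each box. Immediate-early genes have medians of 2.01 and 2.99 in Adipocyte progenitor and Pre-adipocyte and lie below 0 in the other classes.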

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

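Of the tests in this part, that of reads given to a wrong library was written before its result was seen, and those of unrelated droplets and of RNA of 1 cell in more than 1 library were chosen only after the result was seen. The comparisons between classes do not use barcodes outside the retained cells. Shared passing barcodes are among the cells compared, and the report also gives shares with each barcode kept once per sample and the share of barcodes not passing that lay in clusters of non-stromal types.

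Outside the retained cells, endothelial-like clusters, led by Cdh5, Kdr and Emcn, held 218 barcodes, against an allowance of 3 for a count of 0. B-lineage-like clusters, led by Vpreb1, Ighm and Igll1, genes of early B cells, held 455 barcodes. Erythroid-like clusters, led by hemoglobin genes and Slc4a1, held 259 barcodes, 114 of Stroma1 and 145 of Stroma2, but 69 and 42 at Leiden resolution 0.5 and 136 and 219 at 2.0. Neutrophil-like clusters, led by S100a9, S100a8 and Ngp, held 37 barcodes. Megakaryocyte-like clusters, led by Pf4, Ppbp and Itga2b, held 20 barcodes. A fibroblast-like cluster, led by Rgs5, Clec3b and Pi16, held 43 barcodes, 20 of Stroma1 and 23 of Stroma2, but 10 and 18 at resolution 0.5. Rgs5 and Acta2, among its leading genes, are preset markers of mural cells, so the cluster may hold more than 1 cell type. At resolution 0.5 Rgs5 was instead among the leading genes of the endothelial-like cluster. No control samples exist for these numbers, and the names rest on marker genes alone. The sort was against CD45, Ter119 and CD31, which blood, red and endothelial cells carry.

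Libraries of the same sample shared 293 passing barcodes where 9.66 were expected from unrelated droplets, and 486 barcodes not passing where 6.90 were expected, while libraries of different samples shared 18 (12.2 expected) and 3 (6.65 expected). Unrelated droplets with the same barcode are argued against by the excess within samples, 30.3 times the expected number for passing barcodes. RNA of 1 cell in more than 1 library remains a candidate explanation: 88.4% of shared pairs (259 of 293, exact 95% interval 84.2 to 91.8) had the same class where 26.8% were expected, but reads given to a wrong library would give this as well. For wrong-library reads the test set in advance took only the 236 barcodes, passing or not, whose larger copy had 5000 counts or more: the smaller copy had a median of 20.3% of the larger one's counts (quartiles 10.9 and 38.7), at the threshold of 20, so these explanations cannot be told apart. Without that limit the medians per pair of libraries of 1 sample were 51.9% to 53.4% for passing barcodes and 32.9% to 40.4% for those not passing. Barcodes with a filter label have at least 500 counts, so smaller copies are missing from all these values. No biological explanation was tested, and such copies made up 3.38% of the cells of Stroma1 and 12.2% of those of Stroma2.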

How the results depend on the processing

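Tests added only after the result was seen are those with clustering at Leiden resolution 1.0, with 1 barcode per sample, without the collagen I genes, without the cartilage barcode and against MSC alone; the others were planned. Of 172 counts of calls, over 12 results and 16 settings, 161 stayed within 1.5 times the count reported. Of 2702 gene values, 2547 kept direction and side of the threshold, 92 kept direction but lost the call, 32 gained it and 31 reversed. Clustering again did not recover Pre-osteoblast/chondrocyte in any setting, recovered Pre-adipocyte only at resolution 2.0, and recovered 21.8% to 50.7% of Osteoblast progenitor but 97.7% to 100% of Pro-osteoblast, so classes that were not recovered have no value there and are missing from the mean that the others were compared with. A filter of 30 cells gave no value for Pre-osteoblast/chondrocyte. With no low-count filter the median change of all genes was 0.28 in MSC, −0.36 in Pre-adipocyte and −0.48 in Pre-osteoblast/chondrocyte, beside 0.02, 0.02 and −0.06, and in Pro-osteoblast DESeq2 size factors moved it from 0.03 to −0.08. Depth limits Pre-osteoblast/chondrocyte most, with 25 cells in Stroma1. The cause was not tested for any value that moved in the lines that follow.

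Without the sample term, that is with no replicate block, 56 preset genes rose and 59 fell in MSC, 86 and 16 in Adipocyte progenitor, 86 and 20 in Pre-adipocyte, 49 and 30 in Osteoblast progenitor, 36 and 34 in Pre-osteoblast/chondrocyte, and 42 and 108 in Pro-osteoblast, and the calls of all 189 named values held. Deviations of classes of the same sample had a median correlation of 0.0147 over 15 pairs of classes (−0.00814 to 0.0366).

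Genes lower in MSC numbered 59 and were 35 with count splitting. Genes lower in Adipocyte progenitor numbered 16 and were 10 with no low-count filter, 10 with a minimum of 30 cells, 31 at Leiden resolution 0.5, 28 at 1.0, 31 with values centred within samples and 26 with count splitting. Genes lower in Osteoblast progenitor numbered 30 and were 10 at resolution 0.5, 15 at 1.0, 14 centred and 5 with count splitting; count splitting gave 35 higher there, moving the share of higher calls from 61.5% to 87.5%. Lists shifted by camera numbered 8, 8, 5, 3, 6 and 9 in MSC, Adipocyte progenitor, Pre-adipocyte, Osteoblast progenitor, Pre-osteoblast/chondrocyte and Pro-osteoblast. With an estimated correlation they numbered 0 in each, with 5, 6, 4, 2, 3 and 8 at an unadjusted p under 0.05, and by fry 10, 9, 12, 7, 10 and 16.

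At Leiden resolution 0.5, the percent of cells in MSC was 60.2, that in Adipocyte progenitor 22.9, and the percent of cells in Osteoblast progenitor 6.64, and MSC held 65.9% of Cxcl12, 64.1% of Kitl, 59.4% of Il7, 62.7% of Csf1, 70.6% of Angpt1 and 64.1% of Vcam1 transcripts. At 1.0, these were 61.4, 18.9 and 8.88. At 2.0, Adipocyte progenitor held 14.3%, the percent of cells in Pre-adipocyte was 10.01, and Osteoblast progenitor held 12.7% and Pro-chondrocyte 0.553%, and MSC held 59.1% of Cxcl12, 58.8% of Kitl, 57.0% of Csf1 and 59.0% of Vcam1. Centred, MSC held 55.4% of cells, Adipocyte progenitor 24.2%, Osteoblast progenitor 9.46% and Pro-chondrocyte 0.553%, and MSC held 60.7% of Cxcl12, 59.9% of Kitl, 58.7% of Csf1 and 59.9% of Vcam1. With 30 neighbours, links over expected were 0.636 for MSC and Adipocyte progenitor, 1.06 for MSC and Osteoblast progenitor, 1.997 for links Osteoblast progenitor - Pre-osteoblast/chondrocyte, and 0.728 for Pre-osteoblast/chondrocyte and Pro-osteoblast.

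Mmp9 in Adipocyte progenitor, at −2.94, was 2.83 at resolution 0.5, 3.34 at 2.0, 2.41 at 1.0 and 1.96 centred. The other reversals were in Osteoblast progenitor. At resolution 0.5, Pparg was −3.18, Chrdl1 −2.37, Cebpa −0.47, Atf3 0.48, Nr4a1 0.91, Cxcl12 −0.49, Vcam1 −0.43 and Kitl −0.35. At 2.0, Pparg was −0.92, Chrdl1 −0.42 and Vcam1 −0.16. At 1.0, Pparg was −0.47, Chrdl1 −0.65 and Nr4a1 0.021. Centred, Chrdl1 was −0.62, Cxcl1 0.30 and Nr4a1 0.25. With count splitting, the log2 fold change of Chrdl1 in Osteoblast progenitor was −0.9996, Pparg was −0.13, Il7 −0.68, Cebpa −0.49, Atf3 0.65, Cxcl1 0.72, Nr4a1 0.51, Cxcl12 −0.077 and Vcam1 −0.29. With a minimum of 30 cells, Chrdl1 was −0.12. Leaving out each sample gives no test, and of 378 such values 1 called gene changed sign: Runx2 in Pre-osteoblast/chondrocyte, with a range of −0.023 to 1.21.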

Other observations

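Of the tests in this part, that of heat shock genes was written before its result was seen, though leaving out the genes it shared with the immediate-early list came later; the tests of lipid genes, endothelial-like, B-lineage-like and erythroid-like barcodes, cartilage genes, osteocyte RNA and osteocyte-like cells were chosen only after the result was seen.

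Of the preset reticular markers, 6 were chosen after their values were seen and compared with MSC alone, and Esm1 and Agt were left out. In each adipocyte class 1 of the 6 passed: Apoe rose by 0.38 in Adipocyte progenitor (SE 0.12, adjusted p = 0.0483) and Lpl, a lipase, fell by 0.39 in Pre-adipocyte (SE 0.14, adjusted p = 0.0494). Adipoq, the adipokine adiponectin, was at 0.25 in Adipocyte progenitor (adjusted p = 0.436) and 0.22 in Pre-adipocyte (adjusted p = 0.395), and Lepr, the leptin receptor, was at 0.02 and −0.01. In Osteoblast progenitor Lepr, Hp, Lpl and Adipoq fell, Lepr by 1.03 and Hp by 1.16. All 6 fell in Pre-osteoblast/chondrocyte, with Lepr at −3.49 and Adipoq at −7.07, and in Pro-osteoblast, with Lepr at −4.78 and Adipoq at −5.69. Of heat shock genes outside the preset lists, Hspa8, a chaperone, rose by 1.46 (SE 0.13) in Adipocyte progenitor and 2.36 (SE 0.13) in Pre-adipocyte, Hsp90aa1 by 1.77 (SE 0.20) and 2.72 (SE 0.20), and Hspb1 by 1.61 (SE 0.25) and 2.26 (SE 0.27), while the mitochondrial chaperone Hspd1 was at 0.19 (adjusted p = 0.937) and 0.40 (adjusted p = 0.601).

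In the 14 Pro-chondrocyte cells, Spp1 was found in 14, Dmp1 in 13 and Mepe in 10. Phex, a gene of phosphate handling in bone, stood at 807 CPM, Ank, a pyrophosphate transporter, at 3289 and Ackr3, a Cxcl12 receptor, at 1365. Col1a1 stood at 2545 CPM beside 63197 in the other classes together, and Alpl and Bglap, osteoblast genes of mineralization, had 0 counts. Sost, an osteocyte Wnt inhibitor, had 2 counts in Stroma1 and 0 in Stroma2. Among other clusters, 10 passing cells, 6 of Stroma1 and 4 of Stroma2, were led by the interferon genes Cxcl9, Cxcl10 and Iigp1. Outside the retained cells, unnamed clusters led by Car1, Rangrf and Mthfd1 and by Atad3a, Qdpr and Nhp2 held 691 and 394 barcodes. These genes were named after their values were seen.

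Immediate-early genes led Adipocyte progenitor and Pre-adipocyte, and a response to handling of the tissue was weighed against steps toward adipocytes. B-lineage-like and erythroid-like barcodes argue against a response alike in every cell type of the tube, since their highest 90th percentile of immediate-early counts was 2.22%, beside medians of 3.84% and 3.88% in Adipocyte progenitor. A handling response of some cells remains a candidate explanation: 7 heat shock genes outside the immediate-early list had a median of 1.46 against MSC in Adipocyte progenitor (1.42 in each sample alone) and 2.26 in Pre-adipocyte (2.51 and 1.70 in the samples alone), and endothelial-like barcodes reached a 90th percentile of 4.08% in the sample where it was lower. Adipocyte progenitor had 90th percentiles of 6.24% and 6.19%. The medians of endothelial-like barcodes were 1.61% and 1.97%, below those of Adipocyte progenitor and above the 0.427% and 0.392% of MSC. Steps toward adipocytes stay open as well, as lipid genes in Pre-adipocyte had a median of 0.046 against MSC (0.62 and 0.36 in the samples alone) with 1 of 9 higher. The medians of the samples lay above 0, as steps toward adipocytes predict and as those of the heat shock genes did. With 1 of 9 genes called, they do not decide between the explanations. No group in the design separates handling from biology, so no biological explanation was tested against a control.

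Osteocyte genes led Pro-chondrocyte, and 3 sources were weighed. Cartilage genes at the level of Pro-osteoblast or above are argued against by both samples together: the 6 cartilage genes had 0 counts, which allows 186 CPM, beside 709 in Pro-osteoblast. Pro-osteoblast is not a class of cartilage cells, and these counts lay in 93 of its 347 cells. Its mean therefore does not give the level of a cartilage cell. In Stroma2 alone 0 counts allow 256 CPM beside 755 in Pro-osteoblast. The 4 cells of Stroma1 allow 679 CPM beside 353 and cannot decide. The joint limit of 186 CPM lies above the 35.9 CPM of MSC, so levels that low are not excluded. Free RNA from osteocytes is argued against by osteocyte genes other than Mepe and Dmp1, which led the pattern: their ratio over MSC was 30.3 in Stroma2 and 38.5 in Stroma1. Osteocyte-like cells remain a candidate explanation, since these genes had ratios over the highest other class of 10.2 in Stroma2 and 17.6 in Stroma1. Without the 15 leading genes of the class, 5 osteocyte genes with 14 and 7 counts remain, with ratios over MSC of 12.04 and 13.9 and over the highest other class of 4.17 and 6.90. This is a hypothesis from 14 cells, and the labels name no osteocyte group to test it.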
